A study of Homo sapiens with 24 samples.

How the data were processed

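The deposited non-normalized table gave, for each of the 24 arrays, an intensity (the bead summary signal of a probe) and a detection p-value in steps of 1/770, per the file headers and the values. The deposited processed table gave 1 intensity per probe and array on a linear scale. Judged by its values, it had been quantile normalized between arrays without background subtraction. In 24 of 24 columns the processed values matched their own array's signal best, with a rank correlation of 1. The submitters' processing notes name GenomeStudio 2010.1 and Partek without saying what each did, and per the labels RNA was extracted with Trizol and RNeasy columns and made into biotin-labelled cRNA with an Ambion Illumina TotalPrep kit.

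Everything from here on was computed from the authors' deposited signals, with limma 3.58.1 in R 4.3.3, and the plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Signals were corrected for background with a normal-exponential model that used the detection p-values, quantile normalized, given an offset of 16 and put on a log2 scale (limma's neqc). Of 47323 probes, 30113 were listed with 1 gene symbol, 8 with several and 17202 with none. A probe was kept if its detection p was under 0.01 on at least 2 arrays, which 21608 probes met. Where a gene had several kept probes, the one with the highest mean log2 level stood for it (3479 genes), which left 12141 genes tested. The 4992 kept probes without a listed gene were tested apart.

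One limma model with a coefficient for each of the 12 groups was fitted to all 24 arrays, so that the groups shared 1 estimate of spread with 12 residual degrees of freedom (prior degrees of freedom 4.44). The 19 comparisons were contrasts of this model: each line against the control line, the lines against each other, each inhibitor against DMSO in its line, LY294002 averaged within the 3 lines, and the differences between lines in an inhibitor's effect. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was said to rise or fall when its adjusted p was under 0.05. The labels call the arrays of a group biological replicates and share only a replicate number between groups. The p-values measure the spread between these arrays, which may be partly technical, and the number of arrays limits the precision. The median standard error was 0.129 in a comparison of 2 groups, 0.0746 for LY294002 over the 3 lines and 0.183 for a difference between lines. The groups, the comparisons, the model, the gene lists, the alternatives and the reversal measure were chosen before the data were examined. Later additions are named as such where they appear.

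A gene was called below background on an array when its detection p was 0.01 or more. Where a gene was below background on every array of 1 group, its change is given as "at least" a fold: the mean of the other group against the mean of, on each array, the higher of the gene's own level and the lowest level among probes detected there. No fold is given where both groups were below background on every array. The named genes were chosen by rule: every transgene probe, the 8 largest rises and falls of each line against control among genes past the threshold whose groups did not overlap, the 4 largest of each inhibitor comparison, the 3 largest of each difference between lines, the 2 genes with the smallest p where none passed, and up to 4 members with the smallest p of each list described. Not every gene that this rule named is printed. Other genes were named after their values were seen.

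The 30 gene lists, of which 26 had at least 4 tested members and were used, were written from general knowledge. They were Wnt/beta-catenin targets, epithelial junction and keratin, mesenchymal, invasion, matrix and integrins, actin cytoskeleton, colonocyte differentiation, G1/S and replication, G2/M and mitosis, histone genes, p53 targets, ribosome biogenesis, ribosomal proteins, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, ATF4 and amino acid synthesis, the unfolded protein response, lysosome and autophagy, FOXO targets, ERK pathway feedback, AP-1 and immediate early genes, NF-kB and chemokines, the interferon response, Notch targets, circadian and PAR bZIP genes and housekeeping genes. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 26 lists of a comparison. The test was repeated with a correlation estimated from the data. Lists past an adjusted p of 0.05 were described, at most 6 per comparison, beside those that the question of the comparison named. Leukocyte, fibroblast, endothelial and hepatocyte marker lists had 3 of 12, 2 of 10, 1 of 9 and 1 of 8 members measured and were not tested as lists.

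The reversal measure asks how far an inhibitor moved a line's difference from control back towards control. It is minus the covariance over genes of the line's difference from control with the inhibitor's effect, where the DMSO array used for the first is never used for the second. It is divided by the covariance of the 2 estimates of the line's difference that the 2 DMSO arrays give, and averaged over both ways of assigning those arrays. By definition 1 stands for full return along the line's difference from control and 0 for none. It has no test. The overlaps between comparisons that share arrays were set beside the overlap of independent lists of the same sizes. They were also set beside 100 simulations of lines that did not differ from control. In these, noise was drawn for each gene and array on its own, so they show only such noise of the shared control arrays.

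The steps were tested on simulated data, with known differences added to a random share of the genes on the spread of these arrays. Differences of log2 0.58, 1 and 2 were found in 59.7%, 92.5% and 100% of genes for a line against control, and in 28.4%, 76.1% and 100% for a difference between lines in an inhibitor's effect. For LY294002 over the 3 lines 95.5% were found at 0.58. With a true reversal of 0.5 the measure gave 0.446 over 20 simulations, since both estimates in its denominator share the control arrays. An alternative added after this was seen, in which each estimate has its own control array, gave 0.501.

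The median log2 difference of all genes was at most 0.033 in size over the 19 comparisons and 3 scalings of the data. Y-linked genes and XIST were tested with the other genes and are not named.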

Results

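RNA levels were measured on Illumina HumanHT-12 v4 bead arrays in SW480 cells, a line from a human colon cancer, that had been stably transduced with a pBABE-puro retroviral vector. There were 4 lines: a control line and lines labelled BOP1, CKS2 and NFIL3 after the gene introduced. BOP1 is needed for ribosome biogenesis, CKS2 binds cyclin-dependent kinases and NFIL3 is a transcription factor of the bZIP family. Cells were kept for 24 h in the solvent DMSO or in an inhibitor. The BOP1, CKS2 and NFIL3 lines all received LY294002 (PI3 kinase, 3.3 µM). The BOP1 line also received SP600125 (JNK, 33.3 nM) and DAPT (gamma-secretase, which Notch signalling needs, 667 nM), the CKS2 line SB203580 (p38, 3.3 µM), and the NFIL3 line SB203580 and Rapamycin (mTOR, 33.3 nM). The control line was measured in DMSO only. Each of the 12 groups had 2 arrays, 24 in all. Mean raw signal per array ran from 971 to 1366, and 17984 to 19958 probes were detected, 38.0% to 42.2% of those on the array. Replicates correlated across genes at r = 0.991 to 0.996, where genes are not independent replicates.

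The first question was whether the introduced genes could be seen on the arrays. The BOP1 probe was lower in the BOP1 line than in the control line, with log2 means of 12.89 and 13.45 (difference -0.56, SE 0.09, limma adjusted p = 0.00187 over all probes). It was also lower in the CKS2 line (-0.61) and in the NFIL3 line (-0.52), there with an adjusted p of 0.0597 when only the arrays compared were used. In the CKS2 line the CKS2 probes stood at -0.13 (SE 0.11, adjusted p = 0.499) and -0.43 (SE 0.12, adjusted p = 0.0247) against control. NFIL3 had log2 means of 10.42 in the NFIL3 line and 10.43 in the control line (adjusted p = 0.986). No probe of an introduced gene was higher in its own line. Where these probes lie relative to the inserted cDNAs is not given in the sources used here, so the line labels cannot be checked from them.

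What separated the BOP1, CKS2 and NFIL3 lines from the control line in DMSO was the next question. The genes with the largest changes were much the same in all 3 lines. TAGLN, which encodes the actin-binding protein transgelin, fell most: 7.05-fold in the BOP1 line (log2 -2.82, SE 0.15, adjusted p = 2.01e-08), 8.08-fold in the CKS2 line and 7.24-fold in the NFIL3 line (n = 2 against 2 throughout). MYL9, a myosin regulatory light chain of contractile cells, fell by log2 1.23, 1.32 and 1.18 (SE 0.11). MYL2, another myosin light chain, was at least 2.13-fold lower in the BOP1 line and at least 1.98-fold lower in the NFIL3 line. SUN3 fell by log2 1.31, 1.34 and 1.25 (SE 0.17). Below background on both control arrays, AKR1C3, an aldo-keto reductase of steroid and prostaglandin metabolism, was at least 2.7-fold, 3.35-fold and 2.54-fold higher in the BOP1, CKS2 and NFIL3 lines. HPGD, which breaks down prostaglandins, was at least 2.64-fold higher in the CKS2 line and at least 2.46-fold higher in the NFIL3 line. The transcription factor ATOH8 was at least 1.96-fold, 1.72-fold and 2.05-fold higher. RCAN2, an inhibitor of calcineurin, rose by log2 1.61, 1.48 and 1.62 (SE 0.20). ERV3-1, from an endogenous retrovirus, was at least 1.42-fold, 1.79-fold and 1.5-fold higher. Fewer probes were detected on the control arrays (18085 and 18067) than on any line DMSO array (18435 to 19666), which bears on genes below background in control.

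PADI3, which converts arginine in proteins to citrulline, was at least 2.54-fold higher in the BOP1 line and at least 2.3-fold higher in the CKS2 line. Other genes were named for single lines because they ranked among the largest there, which is no test of a difference between lines. In the BOP1 line PLA2G4C was at least 2.37-fold higher, and DACT1, a regulator of Wnt signalling, was at least 2.01-fold lower. In the CKS2 line DRAXIN was at least 1.75-fold higher and PPID fell by log2 1.29 (SE 0.27). In the NFIL3 line TMT1A was at least 2.87-fold and SSPOP at least 1.51-fold higher, and KRT7, a keratin of simple epithelia, fell by log2 1.30 (SE 0.23). The rule also named genes that are less stable and not all printed. TRIM16L, measured on 1 of 2 arrays of each line, stood at log2 -1.804 in the BOP1 line and -1.817 in the CKS2 line. Over the alternatives and left-out arrays these ran from -2.309 to -0.951 and from -2.244 to -0.963. PRIM2, a subunit of the primase that starts DNA strands, fell by log2 1.30 in the BOP1 line. Its falls of 1.27 in the CKS2 line and 1.19 in the NFIL3 line were lost without CKS2 DMSO replicate 2 (adjusted p = 0.0605), control replicate 2 (0.0604) or NFIL3 DMSO replicate 1 (0.116).

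Enzymes of cholesterol synthesis rose in all 3 lines. Of 17 members tested, 13 rose in each line and none fell, with 15, 13 and 13 when adjusted over the list alone (camera adjusted p = 4.55e-09, 7.75e-10 and 1.28e-08 for BOP1, CKS2 and NFIL3). HMGCS1, which makes the HMG-CoA that the pathway starts from, rose by log2 0.82, 0.93 and 0.84 (SE 0.10). LSS, which closes the sterol rings, rose by 0.72, 0.85 and 0.81, and SC5D by 0.85, 0.76 and 0.83 (SE 0.13). Fatty acid synthesis had 3 of 10 members up in each line, 4, 6 and 7 adjusted over the list alone (camera adjusted p = 0.0021, 0.000596 and 0.001), but adjusted p = 0.102, 0.0639 and 0.0999 with an estimated correlation. The elongase ELOVL6 rose by log2 0.55, 0.51 and 0.64 (SE 0.10), and the acetyl-CoA synthetase ACSS2 rose by 0.91 (SE 0.14) in the NFIL3 line.

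Targets of FOXO transcription factors rose as a group, with 7, 7 and 9 of 20 up and none down, or 10, 9 and 10 adjusted over the list alone (camera adjusted p = 0.000679, 0.000596 and 2.82e-05). KLF6, a zinc finger transcription factor, rose by log2 0.92, 0.92 and 0.82 (SE 0.12), and CCNG2, an atypical cyclin of cells that leave the cycle, by 0.84, 0.94 and 1.00 (SE 0.18). BCL6 rose by 0.74 (SE 0.13) in the NFIL3 line. Ribosome biogenesis, the process that BOP1 serves, went down: 7, 4 and 6 of 23 members fell, 7, 6 and 6 adjusted over the list alone (camera adjusted p = 0.000166, 0.00145 and 5.78e-05). UTP20, a factor of the small subunit processome, fell by log2 0.80, 0.87 and 0.85 (SE 0.15). The nucleolar protein NOLC1 fell by 0.57, 0.47 and 0.48, calls that were lost without control replicate 2 in each line (adjusted p = 0.0558, 0.107 and 0.0927), without replicate 1 of the line itself (0.0666, 0.0763 and 0.0537), without replicate 2 of the CKS2 or NFIL3 line (0.09 and 0.0816) and, for CKS2, without control replicate 1 (0.0541), and in the NFIL3 line also with only the arrays compared (0.0532).

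Glycolysis and hypoxia genes fell. In the BOP1 line 8 of 21 fell and 1 rose, 9 and 1 adjusted over the list alone (camera adjusted p = 7.35e-05). The CKS2 line had 7 that fell, 10 down and 1 up adjusted over the list alone (camera adjusted p = 0.00125, adjusted p = 0.0639 with an estimated correlation), and the NFIL3 line 6 down and 1 up, 7 and 1 adjusted over the list alone (0.0129, adjusted p = 0.129 with an estimated correlation). Hexokinase HK2 fell by log2 0.91 (SE 0.11) in the BOP1 line and 0.66 in the CKS2 line, and BNIP3, which acts in the removal of mitochondria, fell by 0.81 (SE 0.11) in the BOP1 line. P4HA1, a collagen prolyl hydroxylase, fell by 0.68 (SE 0.12) and 0.65 in the same lines. Among G1/S and replication genes 1, 3 and 3 of 22 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00523, 0.00712 and 0.000376; adjusted p = 0.259, 0.317 and 0.161 with an estimated correlation). G2/M and mitosis genes had 1, 2 and 2 of 24 down (camera adjusted p = 0.0305, 0.00228 and 0.00212; adjusted p = 0.626, 0.523 and 0.522 with an estimated correlation). The mitotic kinase PLK1 fell by log2 0.50 in the CKS2 line and 0.55 in the NFIL3 line. Those calls were lost without control replicate 1 (adjusted p = 0.116 and 0.0794), without replicate 1 of the line (0.102 and 0.112) and without CKS2 DMSO replicate 2 (0.0558), and that of the NFIL3 line also with only the arrays compared (0.0675).

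Because the introduced genes had been linked to migration, the epithelial and mesenchymal lists were described in every line, and neither passed the camera test. Of 12 mesenchymal genes 2 rose and 3 fell in the BOP1 line, 2 rose and 4 fell in the CKS2 line and 2 rose and 3 fell in the NFIL3 line, with 5 down in the CKS2 line and the same numbers otherwise when adjusted over the list alone (camera adjusted p = 0.143, 0.177 and 0.12). The median of the list in the CKS2 line was 0.037, while its mean of -0.264 and the test pointed down. Besides TAGLN, the receptor kinase AXL fell by log2 0.56 (SE 0.11) in the NFIL3 line. COL6A1, a chain of collagen VI, went the other way and rose by 0.63, 0.53 and 0.62 (SE 0.12). The smooth muscle actin ACTA2 rose by 0.47, 0.55 and 0.50, but lost its call in the BOP1 line without control replicate 1 (adjusted p = 0.103), control replicate 2 (0.0737), BOP1 DMSO replicate 1 (0.196) or with only the arrays compared (0.067), and in the NFIL3 line without control replicate 1 (0.0806), control replicate 2 (0.0562), NFIL3 DMSO replicate 1 (0.106) or with only the arrays compared (0.0517). Of 18 epithelial junction and keratin genes 1, 2 and 1 rose, with 0, 2 and 1 adjusted over the list alone (camera adjusted p = 0.679, 0.295 and 0.757). In the NFIL3 line their median was -0.011, their mean 0.04 and the test pointed up. The tight junction gene MARVELD3 rose by log2 0.30 in the BOP1 line, but not without any 1 of the 4 arrays (adjusted p = 0.0807 without control replicate 1, 0.227 without control replicate 2, 0.0848 without BOP1 DMSO replicate 1 and 0.234 without BOP1 DMSO replicate 2).

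Wnt/beta-catenin targets, to which the study assigned the introduced genes, did not pass as a group in the lines: 4 rose and 1 fell of 14 in the BOP1 line and 3 rose in each of the others, with 4 up and 1 down, 4 up, and 3 up and 2 down adjusted over the list alone (camera adjusted p = 0.558, 0.348 and 0.846). In the BOP1 and NFIL3 lines their medians of -0.01 and -0.057 lay below 0, while the means of 0.07 and 0.03 and the test pointed up. AXIN2, a feedback inhibitor of the pathway, rose by log2 0.27, 0.34 and 0.37, and SOX4 by 0.49, 0.53 and 0.59. Lysosome and autophagy genes did rise, 6, 5 and 6 of 18 against 1, 1 and 0 that fell, or 9, 7 and 6 up and 2, 2 and 0 down adjusted over the list alone (camera adjusted p = 0.00991, 0.0127 and 0.0131; adjusted p = 0.0504 with an estimated correlation in the NFIL3 line). The autophagy gene GABARAPL1 rose by 0.60, 0.71 and 0.63 and the lysosomal protease gene TPP1 by 0.49, 0.66 and 0.67. Among 14 p53 targets 4, 2 and 3 rose and 1, 1 and 0 fell, 6, 3 and 3 up and 1, 1 and 0 down adjusted over the list alone (camera adjusted p = 0.0467, 0.242 and 0.202; adjusted p = 0.102 with an estimated correlation in the BOP1 line), with GDF15, a stress-induced cytokine, up by 1.15 in the CKS2 line. Of 14 invasion, matrix and integrin genes 3, 4 and 5 rose and 0, 0 and 1 fell, 6, 4 and 5 up and 1 down in each line adjusted over the list alone (camera adjusted p = 0.242, 0.185 and 0.045; adjusted p = 0.377 with an estimated correlation in the NFIL3 line). The collagen receptor subunit ITGA2 rose by 0.99, 0.87 and 1.01 and ITGB4, an integrin subunit of epithelial cells, by 0.42, 0.39 and 0.42. The actin cytoskeleton list, which holds MYL9, had 1 of 23 up and 2, 2 and 3 down, 2, 3 and 3 down adjusted over the list alone (camera adjusted p = 0.213, 0.255 and 0.0803).

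**Figure D1:**
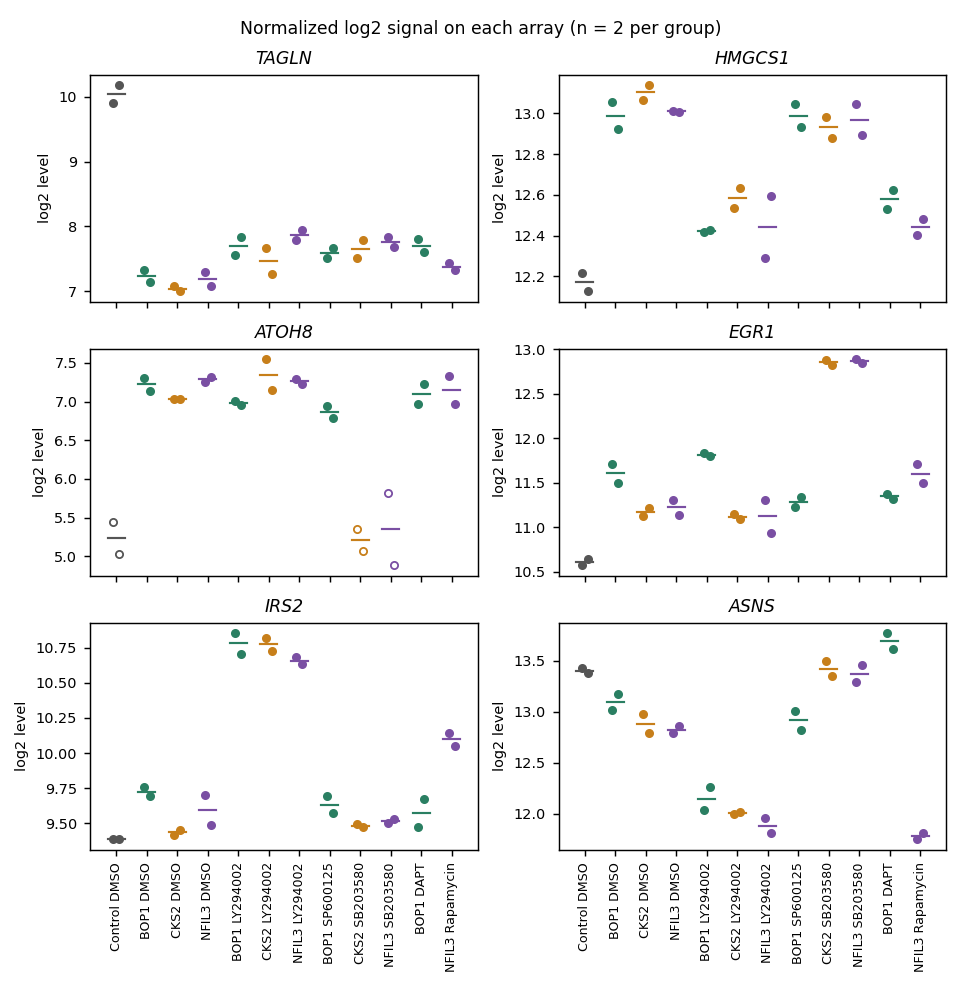
Log2 level of TAGLN, HMGCS1, ATOH8, EGR1, IRS2 and ASNS on each array (vertical axis) in the 12 groups (horizontal axis); points are arrays, filled where detected and open where below background, and lines are means of 2. TAGLN was log2 2.82 to 3.01 lower in the 3 DMSO lines than in control, IRS2 rose with LY294002 and EGR1 with SB203580.

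In all, 1003 genes rose and 621 fell in the BOP1 line, 1004 and 657 in the CKS2 line, and 1059 and 657 in the NFIL3 line. More than 2-fold changes were 63 rises and 22 falls, 72 and 20, and 69 and 27. Each total shrank when an array was left out. The BOP1 total of 1624 became 754 without control replicate 1, 592 without control replicate 2, 531 without BOP1 DMSO replicate 1 and 638 without replicate 2. The CKS2 total of 1661 became 792 and 677 without control replicates 1 and 2, and 617 and 646 without CKS2 DMSO replicates 1 and 2. The NFIL3 total of 1716 became 858 and 686 without control replicates 1 and 2, 598 and 992 without NFIL3 DMSO replicates 1 and 2, and 667 with only the arrays of the 2 groups.

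**Figure D2:**
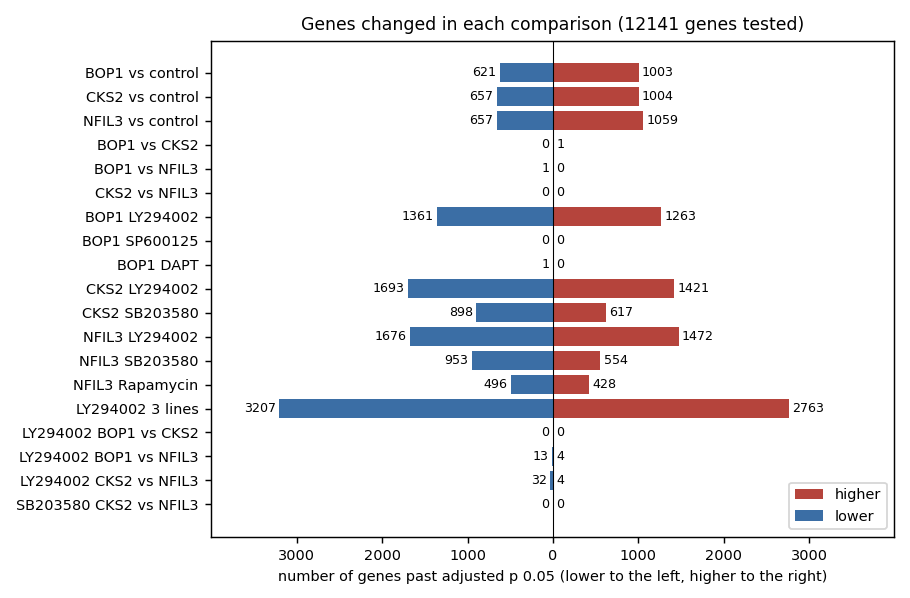
Genes that fell (bars to the left) and rose (bars to the right) at a limma adjusted p under 0.05 in each of the 19 comparisons; the horizontal axis counts genes. LY294002 over the 3 lines had the longest bars, 3207 down and 2763 up, and SP600125 in the BOP1 line had none.

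How much the 3 lines shared was asked next. In the same direction in all 3 lines, 606 genes rose and 270 fell, of 2633 called in at least 1 line, and 0 were called in opposite directions. AKR1C3, ATOH8 and RCAN2 were among the shared rises, and TAGLN, MYL9 and SUN3 among the shared falls. The BOP1 and CKS2 lines shared 752 rises and 390 falls, where 82.9 and 33.6 would be shared by independent lists of those sizes. The BOP1 and NFIL3 lines shared 693 and 333, and the CKS2 and NFIL3 lines 705 and 371. Simulations of lines that did not differ from the same control arrays, with noise drawn for each gene on its own, gave 0, 0 and 0.01 shared genes on average. Such noise rarely passes an adjusted threshold, so a number near 0 was fixed in advance. Across genes, which are not independent replicates, the differences from control correlated at r = 0.885, 0.83 and 0.843, against 0.501, 0.5 and 0.5 from the noise of the shared control arrays in those simulations. When the lines compared had no array in common, r was 0.606 to 0.664. The noise of single shared arrays cannot enter there, so the simulated values near 0.5 are not the reference for it. Part of the excess may come from the control arrays that the 3 comparisons share, and the 876 shared genes became 405 without control replicate 1, 321 without control replicate 2, 404 and 457 without BOP1 DMSO replicates 1 and 2, 455 and 452 without CKS2 DMSO replicates 1 and 2, and 439 without NFIL3 DMSO replicate 1.

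Compared with each other, where the control arrays drop out, almost no gene passed the threshold between the lines. This does not show that the lines were alike. In simulated data for the BOP1 and CKS2 lines, 58.2% of differences of log2 0.58 were found. At a limma p under 0.05 there were 435 genes between the BOP1 and CKS2 lines and 933 between the BOP1 and NFIL3 lines. DDIT3, a stress-induced transcription factor also known as CHOP, was the only gene past the threshold between the BOP1 and CKS2 lines, higher by log2 0.84 in the BOP1 line (SE 0.11, adjusted p = 0.00889). Without BOP1 DMSO replicate 1, BOP1 DMSO replicate 2 or CKS2 DMSO replicate 2 its adjusted p was 0.414, 0.0822 or 0.507, and with only the arrays compared it was 0.368. NMB, which encodes the peptide neuromedin B, was lower by log2 0.70 in the BOP1 than in the NFIL3 line (SE 0.09, adjusted p = 0.0136) but did not pass without any 1 of the 4 arrays (0.144 and 0.231 without BOP1 DMSO replicates 1 and 2, 0.469 and 0.0854 without NFIL3 DMSO replicates 1 and 2) nor with only the arrays compared (0.277). Between the CKS2 and NFIL3 lines limma found 0 genes, with 793 at p under 0.05; ZNF248 stood at log2 -0.70 (SE 0.12, adjusted p = 0.188). Against the CKS2 line, the BOP1 line had higher NF-kB and chemokine genes (0 of 9 past the threshold, 4 up adjusted over the list alone, camera adjusted p = 0.000298), ATF4 and amino acid genes (1 of 19 up, 1 adjusted over the list alone, 0.000401) and AP-1 and immediate early genes (0 of 15, 3 up adjusted over the list alone, 0.00116). TNFAIP3, measured on 1 of 2 CKS2 arrays, and RELB stood at log2 0.73 each, ATF3 at 0.59 and JUN at 0.50 in that comparison. Against the NFIL3 line the camera adjusted p was 0.000791 for both the NF-kB list (0 past the threshold, 3 up adjusted over the list alone) and the ATF4 list (0 past the threshold, 3 up adjusted over the list alone). It was 0.0144 for lower glycolysis and hypoxia genes (0 past the threshold, 4 down adjusted over the list alone, adjusted p = 0.226 with an estimated correlation) and 0.0381 for higher AP-1 genes (0 past the threshold, 3 up adjusted over the list alone, adjusted p = 0.171 with an estimated correlation). No list passed between the CKS2 and NFIL3 lines.

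LY294002, an inhibitor of PI3 kinase, was given to the 3 lines. Whether its effects ran through PI3 kinase was not tested. The signal of MIR21, a microRNA gene, rose from below background on all 6 DMSO arrays of these lines (limma adjusted p = 2.42e-09 over the 3 lines). The rise was at least 1.44-fold in BOP1 and 2.09-fold in NFIL3 cells. Averaged within the lines (n = 6 against 6), LY294002 raised the signal of the histone gene H4C14 by log2 1.40 (SE 0.06) and of GCHFR by 1.41 (SE 0.12). That of RN7SK, the small nuclear RNA that holds the elongation factor P-TEFb, rose by 1.41 (SE 0.08). Whether the signals of histone and small RNA genes follow the amounts of these RNAs was not tested. The laminin chain gene LAMA2 fell by 2.00 (SE 0.10, adjusted p = 1.09e-09), LONRF2 by 1.83 (SE 0.07), MRAP2 by 1.64 (SE 0.08) and SPP1, which encodes the secreted protein osteopontin, by 1.60 (SE 0.10). In total 2763 genes rose and 3207 fell, 49.2% of those tested. Left-out arrays moved the total only between 5368 and 5879.

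All 24 of 24 G2/M and mitosis genes fell with LY294002, and 24 when adjusted over the list alone (camera adjusted p = 5.19e-11, adjusted p = 0.162 with an estimated correlation). Among them the cyclin gene CCNB1 fell by log2 0.77 (SE 0.07), BIRC5 by 0.75 (SE 0.07) and CDC20 by 0.65 (SE 0.06). Of 22 G1/S and replication genes 18 fell, 18 also adjusted over the list alone (camera adjusted p = 3.07e-06, adjusted p = 0.0923 with an estimated correlation), with the ribonucleotide reductase subunit RRM1 down by 0.50 (SE 0.05). In the ribosome biogenesis list 20 of 23 fell, 20 adjusted over the list alone (camera adjusted p = 6.18e-06), among them the helicase DDX21 by 0.55 (SE 0.07). ATF4 and amino acid synthesis genes had 12 of 19 down, 12 adjusted over the list alone (camera adjusted p = 4.03e-05). Here ASNS, the asparagine synthetase, fell by 0.92 (SE 0.06), PHGDH, the first enzyme of serine synthesis, by 0.82 (SE 0.06) and the amino acid transporter SLC7A5 by 0.74 (SE 0.06).

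Targets of FOXO factors, which AKT keeps out of the nucleus, rose with LY294002: 15 of 20 rose and 1 fell, 15 and 1 adjusted over the list alone (camera adjusted p = 2.19e-05). IRS2, an adaptor of the insulin receptor, rose by log2 1.15 (SE 0.05), YPEL3 by 1.30 (SE 0.09) and CITED2 by 0.71 (SE 0.07), while SESN3, a FOXO target in other cells that was measured on 5 of 6 arrays of each kind, fell by 0.35. Histone genes had 9 of 11 up and 1 down, 9 and 1 adjusted over the list alone (camera adjusted p = 8.24e-05). The signal of H2BC5 rose by 1.18 (SE 0.09) and that of H2AC18 by 1.12 (SE 0.08), and that of the variant histone gene H2AZ1 fell by 0.32. AP-1 and immediate early genes had 9 of 15 up and 1, SRF, down, the same adjusted over the list alone (camera adjusted p = 0.000957). Cholesterol synthesis had 12 of 17 down, 14 adjusted over the list alone (0.000323), and the unfolded protein response 11 of 16 down, 11 adjusted over the list alone (0.000849). HMGCS1, higher in each line than in control, fell by 0.55 with LY294002.

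In the single lines LY294002 raised 1263 genes and lowered 1361 in BOP1 cells, 1421 and 1693 in CKS2 cells, and 1472 and 1676 in NFIL3 cells. LAMA2 fell by log2 2.04, 2.08 and 1.88 (SE 0.17) and LONRF2 by 1.87, 1.81 and 1.80 (SE 0.12). In BOP1 cells SELENOP, which carries selenium, rose by 1.51 (SE 0.14), GBP2 was at least 1.92-fold higher, SPP1 fell by 2.14 (SE 0.17) and NAV3 was at least 2.38-fold lower. In CKS2 cells GCHFR rose by 1.65 (SE 0.21), the ectonucleotidase ENTPD2 was at least 1.93-fold higher, MRAP2 fell by 1.79 (SE 0.14) and the heat shock gene HSPB8 was at least 1.73-fold lower. In NFIL3 cells DST, measured on 1 of 2 DMSO arrays, rose by 2.21 (SE 0.19), LINC00205 was at least 3.35-fold higher, the transcription factor gene PDX1 fell by 1.89 (SE 0.12) and NRG4 was at least 1.75-fold lower. FOXO targets had 8, 7 and 10 of 20 up in the BOP1, CKS2 and NFIL3 lines, 11, 8 and 11 adjusted over the list alone (camera adjusted p = 2.53e-05, 0.000154 and 3.38e-05). ATF4 genes had 9, 8 and 8 of 19 down, 9, 9 and 9 adjusted over the list alone (2.53e-05, 0.000154 and 0.000103).

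Mitotic genes had 17, 20 and 19 of 24 down in the single lines, 22, 23 and 24 adjusted over the list alone (camera adjusted p = 2.5e-09, 3.95e-10 and 2.35e-11), but adjusted p = 0.214, 0.184 and 0.169 with an estimated correlation. G1/S genes had 12, 11 and 16 of 22 down, 14, 13 and 17 adjusted over the list alone (2.38e-05, 0.000116 and 1.72e-06), but adjusted p = 0.131, 0.15 and 0.084 with an estimated correlation. Histone genes had 8, 8 and 7 of 11 up and 1 down in each line, 8, 9 and 8 up and 1, 1 and 2 down adjusted over the list alone (4.5e-05, 3.45e-05 and 0.000361), with H4C14 up by log2 1.62 (SE 0.11) in CKS2 cells. Ribosome biogenesis genes had 7, 11 and 12 of 23 down and 0, 0 and 1 up, 7, 14 and 15 down adjusted over the list alone (4.5e-05, 0.000174 and 1.79e-05). The totals shrank without single arrays: the BOP1 total of 2624 became 1320 and 1385 without DMSO replicates 1 and 2 and 1341 without LY294002 replicate 1, the CKS2 total of 3114 became 1784 and 1659 without DMSO replicates 1 and 2 and 1988 without LY294002 replicate 2, and the NFIL3 total of 3148 became 1635 without DMSO replicate 2 and 1656 without LY294002 replicate 2. With only the arrays compared they were 1185, 1230 and 1731.

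Did LY294002 act differently from line to line? Between BOP1 and CKS2 cells limma found 0 genes, with 779 at p under 0.05 and 24 past the threshold without CKS2 LY294002 replicate 1; HOXC8 stood at log2 0.89 (SE 0.18, adjusted p = 0.764). Between BOP1 and NFIL3 cells 4 genes had a higher and 13 a lower effect in BOP1 cells. PDX1 differed by log2 1.11 (SE 0.17, adjusted p = 0.0357), SCFD2 by 1.054 (SE 0.18) and the kinase gene NEK8 by -1.74 (SE 0.33, adjusted p = 0.0486). SCFD2 lost its call with the replicate number as a block. Between CKS2 and NFIL3 cells 4 genes had a higher and 32 a lower effect in CKS2 cells, among them the small Cajal body RNAs SCARNA18 (-1.67, SE 0.27) and SCARNA16 (-1.57, SE 0.25) and the somatostatin receptor gene SSTR2 (-1.59, SE 0.30). No list passed in any of these differences. Leaving out an array took the adjusted p of the named genes up to 0.244 in the first of these comparisons with calls and 0.277 in the second. The 17 genes between BOP1 and NFIL3 cells became 1 and 0 without BOP1 DMSO replicates 1 and 2, 30 and 1 without NFIL3 DMSO replicates 1 and 2, 1 and 2 without BOP1 LY294002 replicates 1 and 2, and 0 without either NFIL3 LY294002 replicate, and 0 with only the arrays compared, with no detection filter or with the mean of a gene's probes. They became 153 with the authors' processed values, 178 without background correction and 35 with detection on all 24 arrays. The 36 between CKS2 and NFIL3 cells became 15 and 0 without CKS2 DMSO replicates 1 and 2, 84 and 1 without NFIL3 DMSO replicates 1 and 2, 158 without CKS2 LY294002 replicate 2, 9 and 0 without NFIL3 LY294002 replicates 1 and 2, 0 with only the arrays compared, 7 with no detection filter, 5 with the mean of a gene's probes, 100 with detection on all 24 arrays, 176 with the authors' processed values and 186 without background correction.

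**Figure D3:**
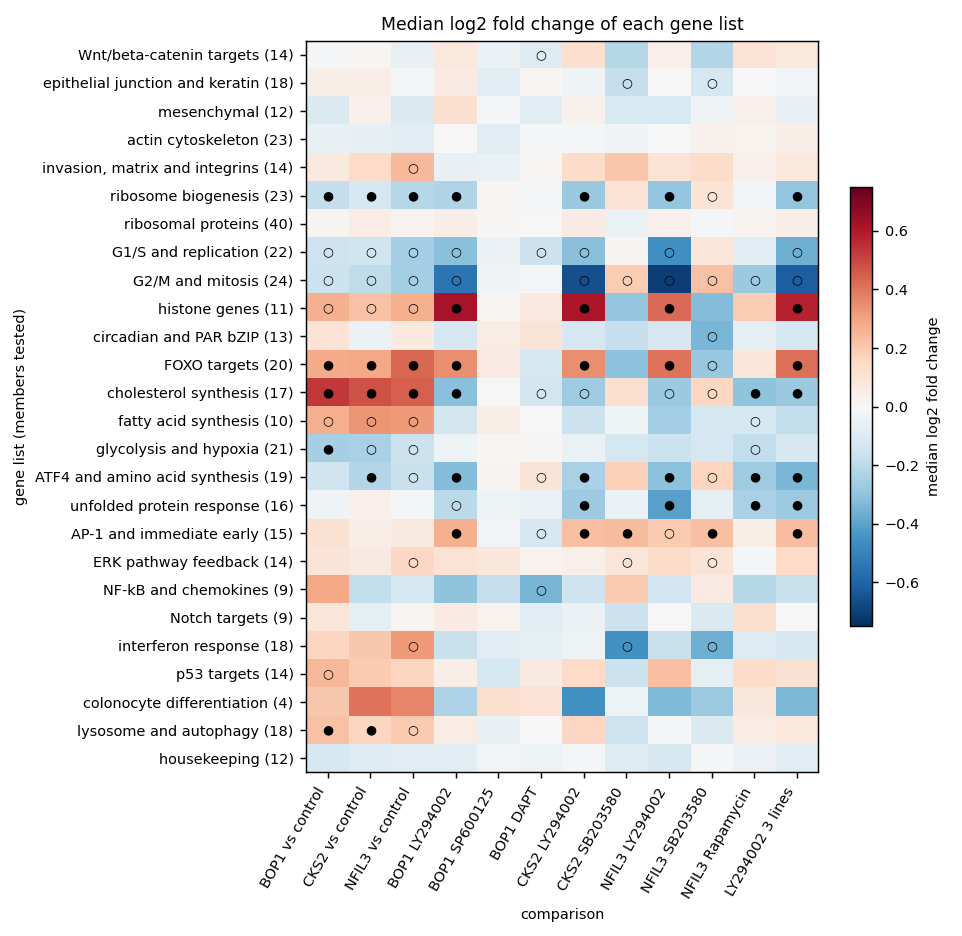
Median log2 difference of each gene list (rows, members tested in brackets) in 12 comparisons (columns), by colour. Filled dots mark lists past a camera adjusted p of 0.05 also with an estimated correlation, open dots those past camera only; cholesterol synthesis rose by a median of 0.53, 0.477 and 0.451 in the 3 lines, and mitotic genes fell by 0.619 with LY294002 over the 3 lines.

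SB203580, an inhibitor of p38, was given to CKS2 and NFIL3 cells. Whether its effects ran through p38 was not tested. EGR1, an immediate early transcription factor, rose by log2 1.68 in CKS2 cells (SE 0.12, adjusted p = 5.03e-07) and 1.64 in NFIL3 cells. NT5E, an ectoenzyme that makes adenosine, rose by 1.46 (SE 0.11) in CKS2 cells and 1.39 in NFIL3 cells, and in NFIL3 cells KIAA0040 rose by 1.54 (SE 0.15) and WNT7B was at least 2.36-fold higher. KRT80, an epithelial keratin, fell by 2.10 (SE 0.10) and 1.78. ABCA1, which exports cholesterol, was at least 2.11-fold and 2.91-fold lower. ATOH8, which was higher in the lines than in control, was at least 1.85-fold and 2.29-fold lower with SB203580. SAMD11 fell by 1.47 (SE 0.12) in CKS2 cells, and ANXA9, measured on 1 of 2 SB203580 arrays, by 1.77 (SE 0.24) in NFIL3 cells.

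AP-1 and immediate early genes rose with SB203580, 6 of 15 in CKS2 and 7 in NFIL3 cells, or 6 up, and 7 up with 2 down, adjusted over the list alone (camera adjusted p = 0.000294 and 0.000312). JUN rose by log2 1.08 and 1.04 (SE 0.10) and FOS by 1.25 and 1.07 (SE 0.15), the subunits of AP-1. Interferon response genes fell, 7 and 5 of 18, with 11 and 7 adjusted over the list alone (camera adjusted p = 0.00206 and 0.000539, adjusted p = 0.0821 and 0.0756 with an estimated correlation), among them IFIT1 by 0.79 and 0.89 (SE 0.15). G2/M and mitosis genes had medians of 0.191 and 0.219 with 0 of 24 past the threshold in either line and 0 adjusted over the list alone (camera adjusted p = 0.0152 and 0.00124, adjusted p = 0.533 and 0.522 with an estimated correlation). Epithelial genes had 4 of 18 down in CKS2 cells and 3 in NFIL3 cells, 6 and 3 adjusted over the list alone (0.0185 and 0.0493, adjusted p = 0.0821 and 0.152 with an estimated correlation), with the transcription factor gene ELF3 down by 0.74 (SE 0.12) and 0.84. The ERK pathway feedback list had 5 of 14 up and 1 down in CKS2 cells, the same adjusted over the list alone, and 4 up and 1 down in NFIL3 cells (0.0436 and 0.0478, adjusted p = 0.129 and 0.152 with an estimated correlation). Its phosphatase DUSP6 rose by 0.84 in both lines (SE 0.10).

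In NFIL3 cells 5 more lists passed camera, all at an adjusted p of 0.0443 and none with an estimated correlation. The ATF4 list (adjusted p = 0.152 with an estimated correlation) had 5 of 19 up and 2 down, 6 and 3 adjusted over the list alone; the cystine transporter gene SLC7A11 rose by log2 1.22 (SE 0.21), and DDIT4, an inhibitor of mTOR, fell by 0.77 (SE 0.12). Cholesterol synthesis (0.163) had 3 of 17 up and 1 down, 4 and 1 adjusted over the list alone, and LSS, the member that fell, did so by 0.54 with an adjusted p of 0.0579 when only the arrays compared were used. The other lists were ribosome biogenesis (1 of 23 up, 0.152), circadian and PAR bZIP genes (5 of 13 down, 0.152) and FOXO targets (6 of 20 down and 1 up, 0.159). In all 617 genes rose and 898 fell in CKS2 cells and 554 and 953 in NFIL3 cells, of which 341 rose and 543 fell in both and 0 went opposite ways. A test of the difference between the lines found 0 genes with limma, with 470 at p under 0.05, so that no gene can be said to respond in 1 line only. The genes with the smallest p, KCNE5 and PTGER2 (adjusted p = 0.732), were below background in groups compared. The CKS2 total of 1515 became 499 and 751 without DMSO replicates 1 and 2 and 689 and 799 without SB203580 replicates 1 and 2. The NFIL3 total of 1507 became 827 and 676 without DMSO replicates 1 and 2, 866 and 623 without SB203580 replicates 1 and 2, and 478 with only the arrays compared.

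Rapamycin, an inhibitor of mTOR given to NFIL3 cells, raised 428 genes and lowered 496, few of them by much: 19 changed more than 2-fold. SLC1A3, a glutamate and aspartate transporter, fell by log2 1.24 (SE 0.15, adjusted p = 0.000655), and HSPB8 was at least 1.57-fold lower. MORN1 was at least 1.51-fold and ENTPD2 at least 1.27-fold higher. ATF4 and amino acid synthesis genes fell, 6 of 19, or 8 adjusted over the list alone (camera adjusted p = 4.48e-05). ASNS fell by 1.04 (SE 0.11, adjusted p = 2e-04), PHGDH by 0.61 (SE 0.10) and TRIB3, a pseudokinase that ATF4 induces, by 0.62 (SE 0.10). Cholesterol synthesis genes had 7 of 17 down, 11 adjusted over the list alone (camera adjusted p = 1.49e-05), with HMGCS1 down by 0.57 (SE 0.10). The total of 924 became 164 and 260 without DMSO replicates 1 and 2, 341 and 170 without Rapamycin replicates 1 and 2, 553 with no detection filter, and 0 with only the arrays of the 2 groups, where the named genes had adjusted p of 0.0718 (ASNS, SLC1A3, MORN1, ENTPD2 and HSPB8), 0.0733 (HMGCS1), 0.0764 (PHGDH) and 0.0794 (TRIB3).

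With Rapamycin 4 other lists passed camera. The mitotic list had 3 of 24 down, 3 adjusted over the list alone (camera adjusted p = 4.89e-05, adjusted p = 0.411 with an estimated correlation), and the unfolded protein response 3 of 16 down, 4 adjusted over the list alone (0.00181). Glycolysis and hypoxia genes had 4 of 21 down, 7 adjusted over the list alone (0.0455, adjusted p = 0.305 with an estimated correlation), with the aldolase gene ALDOC down by log2 0.74 (SE 0.11; 0.0718 with only the arrays compared). Fatty acid synthesis had 2 of 10 down, 3 adjusted over the list alone (0.0482, adjusted p = 0.372 with an estimated correlation). Ribosomal protein genes, whose translation mTOR controls, had 4 of 40 up, 4 adjusted over the list alone (camera adjusted p = 0.1), and FOXO targets 2 of 20 up and 1 down, 2 and 1 adjusted over the list alone (0.125). IRS2 rose by 0.50 (SE 0.09), a call lost without NFIL3 DMSO replicate 2 (adjusted p = 0.0676) and with only the arrays compared (0.102).

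SP600125 and DAPT were given to BOP1 cells to ask about JNK and Notch signalling, and few genes passed. Whether either inhibitor blocked its target at the dose given was not tested. The low counts therefore cannot tell what JNK or Notch signalling does in these cells. With SP600125 limma found 0 genes, with 1424 at p under 0.05; the antioxidant gene GPX1 stood at log2 -0.60 (SE 0.10, adjusted p = 0.148) and DNPEP at -0.60 (SE 0.11). Of 15 AP-1 and immediate early genes, which JNK feeds, 0 passed and 0 adjusted over the list alone (camera adjusted p = 0.473). FOSL1 stood at -0.47 (SE 0.14, adjusted p = 0.232) and EGR1 at -0.32 (SE 0.12). With DAPT only UCA1, a long noncoding RNA, passed, down by log2 0.98 (SE 0.14, adjusted p = 0.0479), with 1525 genes at p under 0.05. UCA1 lost this call with the replicate number as a block. It did not pass without any 1 of the 4 arrays (0.192 and 0.117 without DMSO replicates 1 and 2, 0.0711 and 0.421 without DAPT replicates 1 and 2), nor with only the arrays compared (0.13) or no detection filter (0.0862), and the authors' processed values gave 37 genes.

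Among Notch targets 0 of 9 passed with DAPT, with 1 up and 1 down adjusted over the list alone (camera adjusted p = 0.77; the median was -0.078, the mean 0.029 and the test pointed down). HES1, a direct Notch target, stood at log2 -0.41 (SE 0.11, adjusted p = 0.161) and HEY1, measured on 1 of 2 DMSO arrays, at 1.07 (SE 0.32, adjusted p = 0.181). Camera passed 6 other lists with 0 members past the threshold, and none of them with an estimated correlation. Cholesterol synthesis pointed down (4 adjusted over the list alone, camera adjusted p = 0.00296, adjusted p = 0.105 with an estimated correlation), as did NF-kB and chemokines (4, 0.00296 and 0.062), G1/S and replication (1, 0.00444 and 0.488), AP-1 (1, 0.0233 and 0.11) and Wnt/beta-catenin targets (0, 0.0466 and 0.488). The ATF4 list pointed up (4 adjusted over the list alone, 0.00769 and 0.105), with ASNS at 0.60 (SE 0.11, adjusted p = 0.0553).

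Whether an inhibitor returned a line towards control was measured across all genes. The value was 0.372 for SB203580 in CKS2 cells (0.411 and 0.334 with the DMSO arrays assigned either way) and 0.329 in NFIL3 cells (0.261 and 0.397), where 1 is full return by definition. In simulation a true 0.5 read as 0.446, and with separate control arrays in the denominator, an alternative added later that read 0.501, the values were 0.436 and 0.388. For LY294002 it was negative, -0.289 in BOP1, -0.368 in CKS2 and -0.585 in NFIL3 cells, which is a move away from control. SP600125 gave 0.067 (0.107 without its replicate 1 and 0.026 without its replicate 2), DAPT 0.094 and Rapamycin -0.1 (-0.036 with no detection filter). Genes that were higher in the lines and fell with SB203580 included HPGD (log2 -0.83 in CKS2 and -1.30 in NFIL3 cells, there measured on 1 of 2 SB203580 arrays), TP53INP1 (-0.84 and -1.04) and COL6A1 (-0.69 and -0.88), which were named after their values were seen. TAGLN, lower in the lines, rose by 0.62 and 0.56 with SB203580. It also rose by 0.47, 0.43 and 0.68 with LY294002 in the BOP1, CKS2 and NFIL3 lines, each a small part of its difference. In BOP1 cells its log2 level was also higher with DAPT (7.798 and 7.596) and SP600125 (7.512 and 7.67) than in DMSO (7.322 and 7.139). In NFIL3 cells it was 7.428 and 7.317 with Rapamycin, against 7.297 and 7.085 in DMSO. MYL9 stood at -0.03 and -0.19 with SB203580. DUSP6 and ITGA2 were higher in the lines and rose further with SB203580, ITGA2 by 1.14 and 0.97. With LY294002 ACTA2, COL6A1 and TP53INP1, higher in the lines, rose by a further 0.52, 0.54 and 0.74 over the 3 lines, while HMGCS1 and LSS, also higher in the lines, fell by 0.55 and 0.23.

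**Figure D4:**
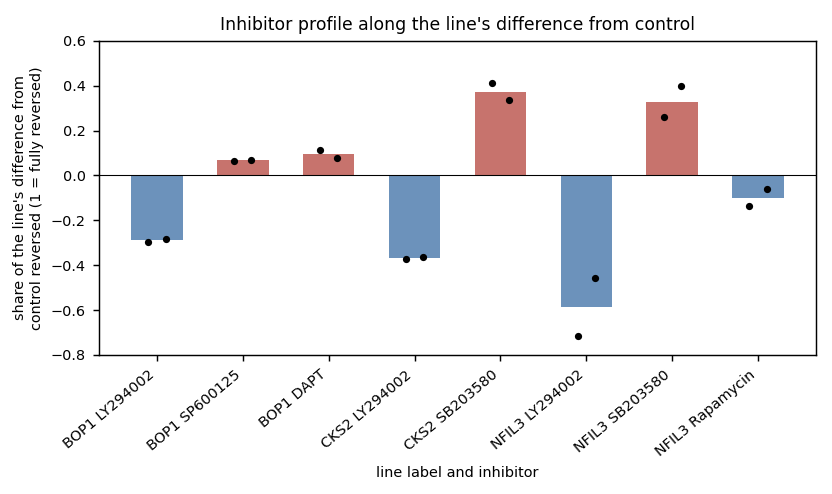
Share of each line's difference from control that an inhibitor reversed (vertical axis, 1 is full return to control by definition), as bars for the mean and points for each of the 2 ways of assigning the DMSO arrays. SB203580 stood at 0.372 and 0.329, and LY294002 below 0 in all 3 lines, from -0.585 to -0.289.

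How alike the inhibitors were was asked with comparisons that share no array. Across genes, which are not independent replicates, LY294002 correlated between lines at r = 0.752 (BOP1 and CKS2), 0.668 (BOP1 and NFIL3) and 0.681 (CKS2 and NFIL3), and SB203580 at 0.735. LY294002 in CKS2 cells and Rapamycin in NFIL3 cells correlated at 0.593, with 297 genes up and 330 down in both and 3 opposite. With LY294002 in BOP1 cells r was 0.481, with 239 up, 247 down and 8 opposite. ASNS, PHGDH and HMGCS1 were among those down with both inhibitors. LY294002 in CKS2 cells and SB203580 in NFIL3 cells stood at r = -0.155, with 376 genes called in opposite directions, 59 up in both and 120 down in both, where independent lists would give 188.8, 64.8 and 132.9. With LY294002 in BOP1 cells r was -0.153, with 355 opposite, 50 up and 85 down in both. TP53INP1 and COL6A1 rose with LY294002 and fell with SB203580, and ASNS did the reverse. The rise of ASNS with SB203580 in NFIL3 cells (log2 0.547, limma adjusted p = 0.00416) lost its call with only the arrays compared.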

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

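No test in this part was chosen after its result was seen. The test of whether an array lies apart from its group was set for groups of at least 4 and was not made here. The arrays of a pair differed most in CKS2 cells with LY294002, by a median of log2 0.182 over genes, against 0.112 to 0.153 in the other groups.

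The effect of LY294002 was tested for a difference between lines, and genes passed in 2 of the 3 pairs of lines. Between BOP1 and NFIL3 cells limma called 17 genes. The effect was higher in BOP1 cells for PDX1 (log2 1.11) and SCFD2 (1.054), and lower for NEK8 (-1.74), all detected on every array compared. For 3 more genes the fitted difference is not a measured size, since a group compared was below background on both arrays: BRIP1 (1.70, NFIL3 with LY294002), AKT2 (-1.97, NFIL3 in DMSO) and WNT7B (-1.61, NFIL3 in DMSO and BOP1 with LY294002). The log2 change of PDX1 with LY294002 was -1.89 in NFIL3 cells and -0.79 in BOP1 cells. BRIP1, PDX1 and SCFD2 shared the smallest adjusted p of these, 0.0357, and with only the arrays compared they stood at 0.0919, 0.0919 and 0.159.

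Between CKS2 and NFIL3 cells limma called 36 genes. The effect was higher in CKS2 cells for PPAN-P2RY11 (log2 1.28, measured on 1 of 2 NFIL3 LY294002 arrays), and lower for SCARNA18 (-1.67), SSTR2 (-1.59) and SCARNA16 (-1.57). The fitted differences of RPL29P2 (1.22) and CCDC69 (1.00) are not measured sizes, since both genes were below background on both arrays of 2 or more groups compared. SCARNA18 and SCARNA16 are small RNAs of Cajal bodies, and the signals of both rose with LY294002 in NFIL3 cells (log2 1.22 and 1.23). Without CKS2 DMSO replicate 2 or NFIL3 LY294002 replicate 2 the count was 0, without NFIL3 DMSO replicate 2 it was 1, without CKS2 LY294002 replicate 2 it was 158, without NFIL3 DMSO replicate 1 it was 84, without CKS2 DMSO replicate 1 it was 15 and without NFIL3 LY294002 replicate 1 it was 9. Without CKS2 LY294002 replicate 1 it was 29. Of the 36 genes, 35 were among the 158, 32 among the 84, 11 among the 15, 10 among the 29 and 9 among the 9.

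Probes with no listed gene were outside every comparison above, and 4992 of them passed the detection filter. In DMSO, 282 of them differed from control in the BOP1 line, 303 in the CKS2 line and 195 in the NFIL3 line. LY294002 changed 1585 over the 3 lines, of which 934 rose and 651 fell. What these probes measure is not given in the sources used here, and they were not analysed further.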

How the results depend on the processing

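The overlap under the alternatives, the reversal with each estimate given its own control array, and the list tests without background correction were chosen after the results were seen. The other alternatives were named beforehand. Leaving out an array of 2 leaves a lone array, assumed to vary like the other groups. The beadchip of each array is not given in the sources used here, so a chip block could not be fitted. The replicate block used the replicate numbers, which only number the arrays: over 66 pairs of groups, arrays of equal number correlated beyond their groups at -0.103 to 0.291 (median -0.001, 3 above 0.1). The genes named by rule gave 458 results over the comparisons, of which 350 passed, and 216 of those passed under every alternative and left-out array; 82 had no value with detection required on all 24 arrays. Of the 82 list results chosen for description by rule, which leave out some that are printed, all kept their call with the authors' values, without background correction and with the replicate block. With an estimated correlation 36 of these did not, and the number of list shifts over all lists and comparisons went from 103 to 47.

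With only the arrays of the groups compared the counts were 667 for NFIL3 against control, 0 for BOP1 against CKS2, 0 for BOP1 against NFIL3, 1185, 1230 and 1731 for LY294002 in BOP1, CKS2 and NFIL3 cells, 478 for SB203580 in NFIL3 cells, 0 for Rapamycin, 0 for DAPT, and 0 for the 2 differences in LY294002 effect with calls. This setting has fewer arrays to estimate the spread from. The authors' processed values gave 4 genes for BOP1 against NFIL3, 2 of them up, 5 for SP600125, 37 for DAPT (20 up), 153 and 176 for the differences of BOP1 and CKS2 from NFIL3 cells in LY294002 effect (10 of the 153 up), and reversals of -0.349 (LY294002, BOP1), 0.057 (SP600125) and -0.446 (LY294002, CKS2). Without background correction these were 4, 7, 39 (22 up), 178 (13 up), 186, -0.354, 0.056 and -0.454. With no detection filter DAPT gave 0, Rapamycin 553, the 2 differences 0 and 7, and the reversals -0.22, 0.071, -0.283 and, for Rapamycin, -0.036. Detection on all 24 arrays gave 4 for BOP1 against NFIL3, 40 for DAPT, 35 and 100 for the differences, and reversals of -0.357, 0.063 and -0.456. The mean of a gene's probes gave 23 for DAPT and 0 and 5 for the differences, and the replicate block 0, 5 and 22. With separate control arrays the reversals were -0.34 (LY294002, BOP1), 0.078 (SP600125), -0.431 (LY294002, CKS2) and 0.436 (SB203580, CKS2). The cause of these changes was not tested.

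Leaving out each array in turn gave 531 to 754 genes for BOP1, 617 to 792 for CKS2 and 598 to 992 for NFIL3 against control, 321 to 591 for their overlap, 0 to 2 for BOP1 against CKS2, 0 to 1 for BOP1 against NFIL3 and 0 to 1 for CKS2 against NFIL3. For LY294002 the range was 1320 to 2092 in BOP1 cells, 1659 to 2854 in CKS2 cells, 1635 to 2374 in NFIL3 cells and 5368 to 5879 over the 3 lines. It was 499 to 799 and 623 to 866 for SB203580 in CKS2 and NFIL3 cells, 164 to 341 for Rapamycin, 0 to 0 for SP600125 and DAPT, 0 to 24, 0 to 30 and 0 to 158 for the differences in LY294002 effect (BOP1 and CKS2, BOP1 and NFIL3, CKS2 and NFIL3) and 0 to 0 for that in SB203580. The reversals ranged from -0.334 to -0.221, -0.486 to -0.25 and -0.656 to -0.5 for LY294002 in the BOP1, CKS2 and NFIL3 lines, 0.026 to 0.107 for SP600125, 0.074 to 0.114 for DAPT, 0.282 to 0.38 and 0.243 to 0.377 for SB203580 and -0.104 to -0.075 for Rapamycin. Values turned direction for NFIL3 in the CKS2 line (-0.091 to 0.016 over the left-out arrays; 0.003 without control replicate 2, 0.016 without CKS2 DMSO replicate 1), NFIL3 in the NFIL3 line (-0.059 to 0.051; 0.037 without control replicate 2, 0.051 without NFIL3 DMSO replicate 2), CKS2 in the NFIL3 line (0.041 without NFIL3 DMSO replicate 2), and with the mean of a gene's probes for DKK1 with DAPT (from -0.26, not past the threshold, to 0.185) and OAS3 with SB203580 in CKS2 cells (from -0.44, adjusted p = 0.0129, to 0.002, adjusted p = 0.995), a call that was also lost without CKS2 DMSO replicate 1 (0.11) or SB203580 replicate 1 (0.0512) or 2 (0.0825).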

Other observations

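Brightness of the control arrays, separate handling of the control arrays and the sharing of DMSO arrays by the SB203580 comparison were tests chosen only after the results were seen, as was the choice of what to note in the first paragraph.

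Lists that did not pass in the lines included colonocyte differentiation (0, 1 and 0 of 4 up and 1, 0 and 1 down, camera adjusted p = 0.999, 0.499 and 0.845) and housekeeping genes (0 of 12 up and 1, 2 and 2 down, 0.128, 0.177 and 0.0803). The iron transporter gene TFRC, on the housekeeping list, fell by log2 0.36, 0.39 and 0.52. Interferon response genes passed in the NFIL3 line only (4 of 18 up, 0.0262, adjusted p = 0.143 with an estimated correlation), which is no test of a difference between lines. Histone genes rose in all 3 lines (3, 3 and 2 of 11, 4, 3 and 2 adjusted over the list alone, camera adjusted p = 0.0286, 0.0192 and 0.023), but had adjusted p = 0.102, 0.0919 and 0.102 with an estimated correlation. Markers of other cell types were measured for 7 genes, and COL1A1, ESAM and ALB were detected on all 24 arrays of these colon cancer cells. ALB rose with LY294002 in each line (log2 0.64, 0.51 and 0.86), COL1A1 rose in the BOP1 line (0.48) and fell with SB203580 (-0.55 and -0.71), ESAM fell in the CKS2 line (-0.39) and rose there with SB203580 (0.53), and CORO1A, detected on 5 arrays, passed in 2 comparisons.

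The 3 lines shared 876 genes that differed from control in the same direction, and each pair of lines shared more genes than independent lists of those sizes would. Unchanged lines against the same control arrays shared almost none in simulation. The simulated noise was drawn for each gene on its own and rarely passes an adjusted threshold, so this outcome was fixed in advance. It excludes no noise that the genes of an array have in common. A single deviant control array was argued against, since 321 genes were still shared without control replicate 2, which is only just above the bound of one in 3 set beforehand, and the line effects correlated across genes at 0.606 or more with no array in common. Brighter control arrays were argued against as well, by mean signal only. That of 3 line arrays was 1257, 1297 and 1365, within 5% of the 1303 to 1366 of the control arrays, 1 of them inside that range. These 3 lay on average at 1.033 on a scale from 0 for the control line to 1 for the other lines. The lowest detected log2 level was higher on the control arrays (6.25 and 6.26) than on the line DMSO arrays (5.88 to 6.16). They also detected fewer probes (18085 and 18067 against 18435 to 19666). What these 2 differences do was not tested. That the control arrays were handled apart from the others cannot be told apart from a line difference, because no chip or day is named; a reversal of 0.372 by SB203580 does not decide it. A shared response to the introduced genes, to the selection of the lines or to the origin of the control line may also be the source, and none of these was tested.

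SB203580 moved CKS2 and NFIL3 cells back along their difference from the control line, the only direction that the measure sees. Principal components sum up the main variation between arrays. On the first (38.99% of the variance) SB203580 arrays (-21.73 to -19.3) stood closer to control (-25.26 and -24.48) than DMSO arrays of these lines (-5.36 to -3.72). On the second (13.55%) they stood at 15.8 to 18.53, further from control (-14.68 and -10.58) than DMSO (-10.36 to -2.2). The measure uses no DMSO array in both of its terms, so the sharing of single arrays does not enter it, and the lowest of its 4 values was 0.261. This is part of the result and not a separate test, and a shift common to both DMSO arrays of a line stays open. A few genes with large changes were argued against by the value without the 100 genes that differed most in the BOP1 line, which was 0.33 in NFIL3 cells and 0.379 in CKS2 cells. That p38 signalling is part of what sets the lines apart from control is a hypothesis found and examined on the same data, and SB203580 was not given to the control line, so that its effect there may be the same.

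The effect of LY294002 differed between CKS2 and NFIL3 cells in 36 genes. The lowest count with 1 of the 8 arrays left out was 0, and 4 of the 8 left-out arrays took the count under one in 3 of 36, which met the bound set beforehand for a deviant array. That test does not decide, a judgement made after its value was seen: the 4 arrays lie in 3 groups (CKS2 DMSO replicate 2, both NFIL3 LY294002 replicates and NFIL3 DMSO replicate 2), so that no array is singled out, and each array left out also costs precision. A deviant array therefore stays open. A shift common to both NFIL3 LY294002 arrays stays open too. On the second principal component over all genes they stood at 17.29 and 17.35, and the other LY294002 arrays at -5.77 to -0.09. What set this pair apart was not tested. Probes near background stay open as well. Of the genes, 31 of 36 (0.861) had at least 1 probe detected on all 24 arrays, which need not be the probe tested. CCDC69, RPL29P2 and PPAN-P2RY11 were among the other 5. For all genes tested the share was 0.837, but there only the tested probe was counted, so the shares are not alike. The bound set beforehand lay below that 0.837, so passing it does not decide. A difference between the lines in their response is possible and stays a hypothesis.

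For LY294002 over the 3 lines, the count was set beside regroupings of the same arrays within lines. In a model with line as a term 5366 genes passed with the real grouping and at most 1 with any of the other regroupings drawn, of which the real one was 1 of 100.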
